A study of Mus musculus with 15 samples.

How the data were processed

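Messenger RNA was measured in 15 libraries of C2C12 mouse myoblasts, 3 in each of 5 groups. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, cells carried lentiviral constructs, and libraries were made with a stranded kit after poly(A) selection. The submitters' processing notes name CASAVA, TopHat2 and STAR and the mouse build mm9, with no role or version. Whether the counting used strand is not given in the sources used here.

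The authors deposited 1 table of log2 FPKM values (fragment counts scaled by transcript length and library depth) for 23352 genes. Its lowest value was exactly 1 in every library, so the deposited values were read as log2(FPKM + 2) and FPKM was taken as 2 to the power of the value, minus 2. An offset of 1 with a lowest value of 0 had been foreseen, and the fit itself used the log2 values as deposited either way. The offset of 2 was taken because FPKM multiplied by RefSeq transcript length then summed to 0.902 to 0.935 M over genes that hold 89.3% of the total. Values of the form 1 + log2(FPKM + 1) would give the same table with every FPKM halved, a reading that the sums argue against. Log2 fold changes are on the log2(FPKM + 2) scale, which understates the change of genes with low values.

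The table gives no counts. Depth was estimated from the steps between low FPKM values, which are whole reads divided by transcript length and depth, over 14094 genes with 1 RefSeq length. It ranged from 38.4 to 82.5 M reads in the GFP control, 53.0 to 77.6 with MLX-WT, 47.0 to 65.9 with MLX-DN, 39.5 to 56.3 with the non-targeting shRNA and 36.9 to 52.0 with MLX shRNA. Between 64.6% and 68.1% of low values lay within 0.05 of a whole number of reads, where 10% would if evenly spread and 23.4% to 27.4% did at other depths within 5% of the estimate. At 2000 bases of transcript 1 read is worth 0.0061 to 0.0135 FPKM, and the floor of 3 reads is 0.0182 to 0.0406 FPKM, which covers counting error only. These are FPKM values, not counts, so no count model was used.

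Genes with an FPKM of at least 1 in at least 3 of the 15 libraries were tested, 11945 in all. The test was limma (3.58.1, in R 4.3.3) on the deposited log2 values with 1 mean per group over all 15 libraries, moderated with a trend over expression, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Comparisons were MLX-WT and MLX-DN against the GFP control, MLX shRNA against the non-targeting shRNA, MLX-DN against MLX-WT, the controls against each other, and the differences of effects. Mean ± SD values are FPKM over the 3 libraries of a group. For 33 gene lists, 29 of which had 5 or more tested members, limma's camera was run with a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over the 29 lists of a comparison. The count adjusted over the list alone uses the same p-values adjusted within that list. With the estimated correlation, the calls that held were interferon and hypoxia response with MLX-WT, cell cycle with MLX-DN, cell cycle and fibroblast markers with MLX shRNA, and interferon response, cholesterol synthesis and cell cycle between MLX-DN and MLX-WT.

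The genes named are the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose mean FPKM is at least 2 in the higher group, leaving out predicted genes, together with Mlx and its network, 2 to 4 of the 4 members of lowest p in each list described, and the 5 of lowest p in each direction for the differences of effects and the controls. The groups, comparisons, tests, gene lists, naming rule and the first set of alternatives were fixed before the data were examined. These alternatives were other offsets, filters, scalings, variance models and sets of libraries, the other control, a 2-fold limit, a replicate block, and leaving out each library in turn. Alternatives chosen after seeing the data were removal of trends over GC content and length, calls in the same direction against both controls, removal of the chromosome 8 run, and the other control for the level of Mlx and the counts of lists. Neighbouring genes were taken from the GRCm38 annotation, which placed 99.5% of the tested genes. No coordinates are printed, since the notes name mm9. Runs were sought among 8389 genes of mean FPKM of at least 5, by medians of 11 neighbours, against 100 random gene orders. Of 127 named genes, 125 had exons in that annotation, and Mlx, Txnip and Ndufb5 shared at least 10% of their exon bases with an expressed gene of the opposite strand (Psmc3ip, Gm15441 and Mrpl47). Their values are uncertain to that extent. Some genes that the naming rule selects are not reported here, and none were put in their place.

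The fit was tested on simulated data for each comparison, with 11945 genes and 50 changed genes per fold size. At 1.25-fold it recovered 88.6% for MLX-WT, 86% for MLX-DN and 87.6% for MLX shRNA. At 1.5-fold it recovered 98.6%, 99% and 98.2%, at 2-fold 99.6%, 99.2% and 99.8%, and at 4-fold 99.8%, 100% and 100%. Of 11715 unchanged genes 0.0965%, 0.0845% and 0.0879% were called, and 10 of 10 planted lists and 0 of 280 unchanged lists passed in each comparison. The simulated genes varied independently of each other, so this gives no rate of false calls for lists whose genes vary together. All members of a planted list were shifted by the same amount among genes that were mostly unchanged. Most genes were called in the real data, so the share of planted lists found does not carry over to it. In the real data up to 6, 6 and 8 lists passed in other splits of the libraries for MLX-WT, MLX-DN and MLX shRNA. The search for runs found 20 of 20 planted runs of 60 genes among 8400 and no other, and simulated depths over 14094 genes and 15 libraries were recovered to within 0.81%. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Promoter sequences were not analysed here.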

Results

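C2C12 is a mouse line of skeletal muscle precursor cells (myoblasts) that can be made to fuse into contractile myotubes. MLX is a basic helix-loop-helix leucine zipper transcription factor that binds DNA as a partner of MLXIP (MondoA), MLXIPL (ChREBP) and members of the MAD family, and the MondoA and ChREBP partnerships are known for raising genes in response to glucose. Messenger RNA was sequenced from C2C12 cells that carried lentiviral constructs for wild-type MLX (MLX-WT), a dominant-negative form (MLX-DN) or a short hairpin RNA against Mlx (MLX shRNA). The controls were a vector expressing only green fluorescent protein (GFP control) and a non-targeting shRNA. Each of the 5 groups had 3 libraries, 15 in all, and the deposited table listed 23352 genes as log2 FPKM. The steps between the lowest FPKM values gave depths of 36.9 to 82.5 M reads per library, with 38.4 to 82.5 M in the GFP control and 36.9 to 52.0 M in the MLX shRNA group. Libraries of the same group correlated at r = 0.998 to 0.999 over the tested genes. In genes with many reads and 1 RefSeq length, the spread between them beyond counting noise was a median of 1.32% of the value in the GFP control (4998 genes). In the MLX shRNA group it was 2.91% (4331 genes). These medians do not describe genes with fewer reads. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

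On the first principal component, which held 50.3% of the variance, the 5 groups were spread out. The GFP control libraries were lowest (-30.2 to -29.7), MLX-WT was nearest to them (-10.6 to -9.9) and MLX shRNA was highest (21.1 to 23.1). The MLX-DN libraries correlated with the non-targeting shRNA libraries at r = 0.986 to 0.989 and with their own GFP control at 0.961 to 0.965. Each comparison below is therefore given against its own control, and values against the other control are given for many of the genes, in particular where they are much smaller or turn.

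**Figure D1:**
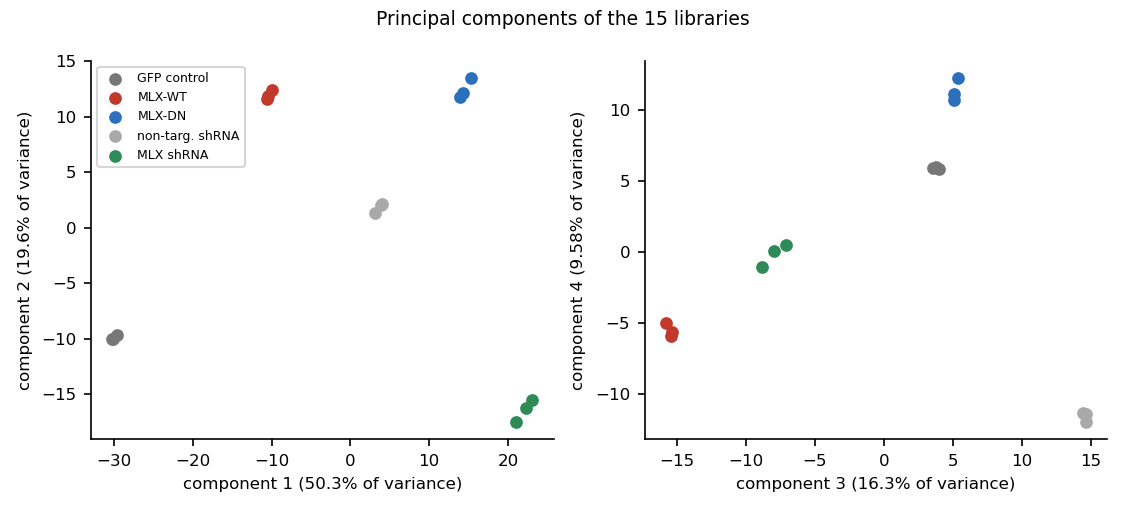
Principal components of the 15 libraries, computed from the log2 values of the tested genes, with each point 1 library and the share of variance on each axis. The 3 libraries of a group fall together, and on component 1 (50.3% of variance) the GFP control libraries have the lowest scores of the 5 groups.

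Mlx itself was read first, because it shows whether each construct raised or lowered the RNA as its label implies. The RNA level does not show dominant-negative action of MLX-DN, as no protein was measured here. Mlx stood at 17.1 ± 0.516 FPKM (mean ± SD, n = 3) in the GFP control and 17.1 ± 0.778 in the non-targeting control. It reached 644 ± 11.6 FPKM with MLX-WT and 394 ± 8.76 with MLX-DN, and it fell to 3.21 ± 0.645 with MLX shRNA. The log2 changes were 5.08 for MLX-WT (SE 0.0596), 4.37 for MLX-DN and -1.88 for MLX shRNA, with limma adjusted p-values of 7.36e-18, 1.37e-17 and 3.76e-13, and all 3 libraries of each group lay on the same side of both controls. The gene overlaps Psmc3ip on the opposite strand (GRCm38 annotation), whose highest group mean was 8.49 FPKM. The values of the MLX-WT and MLX-DN libraries may include reads from the constructs, which the table does not tell apart from the cells' own gene. Mlxip, which encodes MondoA, was expressed at 4.08 FPKM in the GFP control and its log2 differences were -0.13, -0.04 and -0.21 for MLX-WT, MLX-DN and MLX shRNA (adjusted p = 0.0414, 0.540 and 0.00230 by limma). Its call with MLX-WT was lost with median centring, quantile normalization, no filter or removal of trends over GC content and length. It was also lost without GFP control replicate 3 (adjusted p = 0.208) or MLX-WT replicate 1 (0.0572) or 2 (0.156), with 0.000237 to 0.571 over its alternatives. Against the other control Mlxip was at -0.28, -0.19 and -0.06 (adjusted p = 0.000237, 0.00545 and 0.305), so its call with MLX shRNA was lost there. Max, the partner that MYC and the MAD proteins share, was at 0.00 with MLX-WT, 0.12 with MLX-DN and 0.18 with MLX shRNA. Against the other control Max was at -0.11, 0.00 and 0.30, which ended its call with MLX-DN (adjusted p = 0.891). Mycl1, a MYC family gene, rose by 1.04 with MLX-WT and 1.24 with MLX-DN against the GFP control, but its changes against the non-targeting control were -0.27 and -0.07. With MLX shRNA it was at 0.09 against the non-targeting control and 1.40 against the GFP control. Mxd3, a MAD family member, fell with MLX-DN (-0.82 log2) and with MLX shRNA (-0.80). As a list, the 11 tested genes of the MLX network did not pass the camera test in any of these 3 comparisons (adjusted p = 0.220, 0.830 and 0.216). In these comparisons the list had 4, 5 and 3 members higher, 4, 5 and 7 lower, and 8, 10 and 10 changed when adjusted over the list alone.

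**Figure D2:**
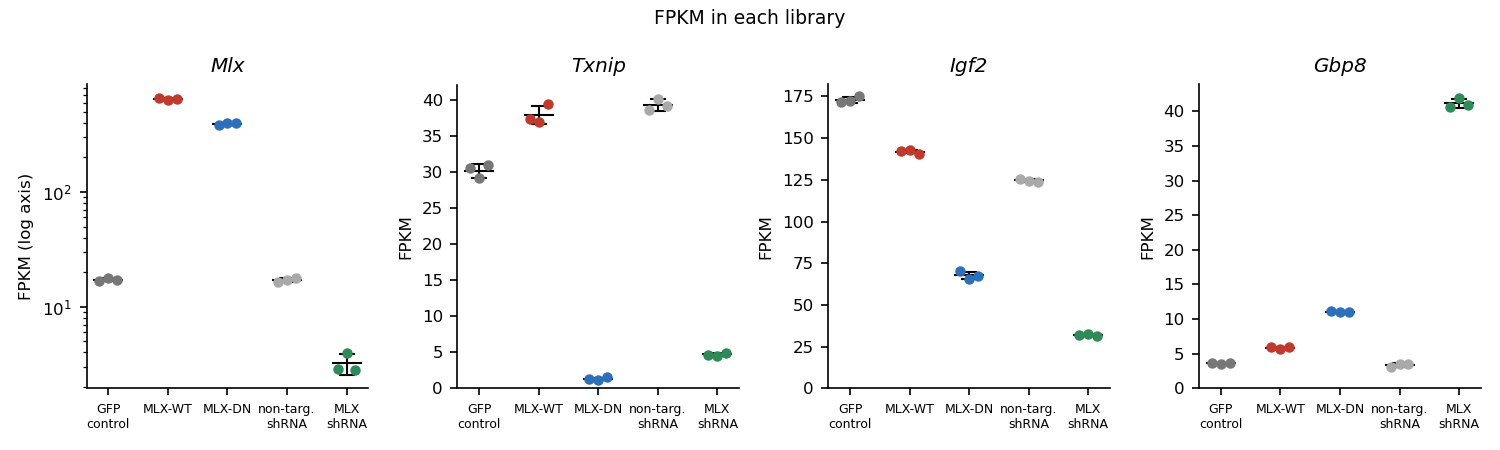
FPKM of Mlx (log axis), Txnip, Igf2 and Gbp8 (linear axes) in each of the 15 libraries, with points for libraries and bars for the mean and SD of 3. Mlx ranges from a mean of 3.21 FPKM with MLX shRNA to 644 with MLX-WT, Txnip and Igf2 are lowest in the MLX-DN and MLX shRNA libraries, and Gbp8 is highest with MLX shRNA at 41.1 FPKM.

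Adding wild-type MLX asks which genes respond to more of the factor. Genes of the interferon response, the hypoxia response and glycolysis rose, and genes of the extracellular matrix fell, against both controls, with camera adjusted p = 3.02e-11, 0.0272, 4.49e-06 and 0.00589 against the non-targeting control. With an estimated correlation the calls of 2 of these lists against the GFP control were lost (adjusted p = 0.498 for glycolysis, where 12 of 21 genes rose, and adjusted p = 0.607 for the matrix). Against the non-targeting control only the interferon list kept its call with an estimated correlation (adjusted p = 0.000456), and hypoxia, glycolysis and the matrix did not (adjusted p = 0.195, 0.195 and 0.431). Bst2 (tetherin, an interferon-induced antiviral protein) went from 9.04 ± 0.480 to 57 ± 2.25 FPKM, a log2 change of 2.42 against the GFP control and 2.45 against the non-targeting control. Enpp2, which encodes autotaxin, the secreted enzyme that makes lysophosphatidic acid, went from 1.22 ± 0.102 to 26.9 ± 0.308 FPKM (3.17 and 3.58). Bgn, the matrix proteoglycan biglycan, fell from 594 ± 2.50 to 175 ± 3.32 FPKM (-1.75 and -1.57).

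Among the 10 largest rises with MLX-WT, apart from Mlx, Myl2 (regulatory myosin light chain of slow muscle) rose by 3.97, Bglap2 (osteocalcin) by 3.30, the surface protein gene Ly6d by 3.04 and Pvalb (parvalbumin, a calcium buffer of fast fibres) by 2.19. Relative to the non-targeting control these 4 rose by 1.49, 2.48, 3.88 and 2.85. The hormone gene Fgf21 (log2 2.62), Igfbp2 (2.29), which encodes a binding protein of insulin-like growth factors, and the keratin gene Krt80 (2.16) were high relative to the GFP control, while against the non-targeting control their values were 0.08, -0.53 and -0.22. Of the 10 largest falls, Ctrb1 (chymotrypsinogen, -2.14) and the calpain-like gene Capn6 (-2.08) also fell against the non-targeting control (-1.16 and -1.17). Gja5 (connexin 40, -2.25), Cdh10 (-1.95), Scn7a (-1.92), the prostaglandin-degrading enzyme gene Hpgd (-1.91), Mybpc1 (slow myosin-binding protein C, -1.89), Crym (-1.87) and the proliferin genes Prl2c4;Prl2c3 (-1.77), which share reads as near copies and are uncertain, were instead higher than in the non-targeting control, by 0.17, 0.27, 0.18, 1.04, 1.49, 0.56 and 0.19. Mylk4, a myosin light chain kinase gene, stood at -1.78 against the GFP control and -0.01 against the other.

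Of 22 tested interferon response genes, 19 rose and 2 fell with MLX-WT (21 changed when adjusted over the list alone; camera adjusted p = 8.37e-08, and adjusted p = 0.00247 with an estimated correlation). Beside Bst2 these included Psmb8, an immunoproteasome subunit (1.10), and Ifih1, a sensor of viral RNA (0.95). Of 18 hypoxia response genes 15 rose and none fell (16 when adjusted over the list alone; adjusted p = 8.37e-08, and adjusted p = 0.00770 with an estimated correlation). They included the mitophagy receptor gene Bnip3 (1.46, and 0.24 against the non-targeting control), Ak4 (1.06 and 0.36) and Pdk1, a kinase that restrains pyruvate oxidation (1.10 against the GFP control, 0.05 against the other). Of 28 genes of ER stress and the ATF4 response 23 rose and 4 fell (27 when adjusted over the list alone; adjusted p = 7.97e-09, and adjusted p = 0.0761 with an estimated correlation). They included the serine and asparagine synthesis genes Psat1 (1.02) and Asns (0.90) and the ER quality control gene Herpud1 (1.04). This list did not pass against the non-targeting control, with a median of -0.13 (adjusted p = 0.266) and Psat1, Asns and Herpud1 were at 0.17, 0.08 and -0.29.

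Of 21 glycolysis genes 12 rose and 5 fell (17 when adjusted over the list alone; adjusted p = 0.00364, and adjusted p = 0.498 with an estimated correlation). Pgk1, phosphoglycerate kinase, rose by 0.65 (0.29 against the non-targeting control), and the lactate transporter gene Slc16a1 by 0.72, although Slc16a1 was at -0.16 against the latter. In the list of pentose phosphate and NADPH genes 7 of 11 rose and 3 fell (10 when adjusted over the list alone; adjusted p = 0.0471, and adjusted p = 0.235 with an estimated correlation). Mthfd2 was at 0.92 and 0.09 against the 2 controls, and G6pdx, the first enzyme of the pathway, at 0.27 and 0.73. Of 11 replication histone genes 7 rose and 1 fell (8 when adjusted over the list alone; adjusted p = 0.0435, and adjusted p = 0.235 with an estimated correlation). They included Hist2h3c1 (0.38 and 0.41) and Hist1h2ac (0.34 and 0.15). Transcripts of these histone genes mostly lack a poly(A) tail, and the libraries were selected for one. Both of these lists lost the call when 1 library was left out: adjusted p = 0.0557 without MLX-WT replicate 1 and 0.065 without GFP control replicate 1 for pentose phosphate and NADPH (0.0161 to 0.235 over its alternatives), and 0.0533 without MLX-WT replicate 1 and 0.0549 without GFP control replicate 3 for the histones (6.94e-05 to 0.235). Both also lost it with an offset of 0.1, quantile normalization, median centring or removal of trends over GC content and length. Pentose phosphate and NADPH lost it with the stricter filter or no trend in the variance as well, and passed in 11 of 20 alternatives, while the histones passed in 12 of 19.

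Genes of the cell cycle fell with MLX-WT, with 30 of 34 lower and 3 higher (33 when adjusted over the list alone; adjusted p = 8.34e-05, and adjusted p = 0.0761 with an estimated correlation). The replication helicase genes Mcm2 (-0.66) and Mcm6 (-0.67) were among them, while the cyclin D1 gene Ccnd1 rose by 0.45. Against the non-targeting control the cell cycle list had a median of 0.06 and did not pass (adjusted p = 0.124), with Mcm2 at -0.16 and Mcm6 at -0.26. Of 33 extracellular matrix genes 23 fell and 8 rose (31 when adjusted over the list alone; adjusted p = 0.00517, and adjusted p = 0.607 with an estimated correlation): Col4a1, a basement membrane collagen, fell (-1.15), and the metalloproteinase inhibitor gene Timp3 rose by 1.09 (-0.76 and 0.13 against the non-targeting control). Of 19 targets of TGF-beta and the serum response factor (SRF) 14 fell and 3 rose (17 when adjusted over the list alone; adjusted p = 0.0139, and adjusted p = 0.498 with an estimated correlation). Tagln (-1.17) and Myl9 (-0.81), which encode proteins of the smooth muscle type of actin filaments, fell and the muscle stress gene Ankrd1 rose (1.23). That list did not pass against the non-targeting control (adjusted p = 0.0988), where Tagln, Myl9 and Ankrd1 were at -0.88, 0.69 and 0.96.

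Lists that define muscle did not pass against the GFP control. Of 49 sarcomere genes 23 rose and 19 fell (42 when adjusted over the list alone; adjusted p = 0.277), with Myl4 at -1.28 and the calcium pump gene Atp2a1 at -0.89. Against the non-targeting control 41 of the 49 were higher and 5 lower (adjusted p = 1.18e-20, and adjusted p = 0.149 with an estimated correlation), and Myl4 and Atp2a1 were at 0.66 and -0.19. Of 18 myogenic regulators 8 rose and 8 fell (16 when adjusted over the list alone; adjusted p = 0.683): the differentiation factor gene Myog was at 0.43 and the RNA-binding protein gene Rbm24 at 0.65, and both were at -0.13 and -0.20 against the non-targeting control. Among secreted muscle factors 22 of 63 rose and 35 fell (57 when adjusted over the list alone; adjusted p = 0.683), with the matrix protein gene Postn at -0.95 (-2.64 against the non-targeting control) and the myostatin inhibitor gene Fst at -0.92 (-0.29). The immediate early genes Egr1 (-1.01 and -0.26 against the 2 controls) and Egr2 (-1.63 and -0.74) and the Notch target Hes1 (-0.63 and -0.64) fell, in lists that did not pass as a whole (adjusted p = 0.893 and 0.965). Of the 15 tested glucose-responsive targets of MLX partners, 6 rose and 8 fell (14 when adjusted over the list alone; adjusted p = 0.683), with a median of -0.13 although the mean and the camera direction were positive, and with Fgf21, the desaturase gene Scd1 (0.58) and Pfkfb3 (0.52) among those of lowest p. Txnip, the thioredoxin-interacting protein gene that is the best known of these targets, was at 0.31 against the GFP control and -0.05 against the non-targeting control.

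By limma, 8400 of 11945 tested genes differed between MLX-WT and the GFP control, 3300 higher and 5100 lower, and 200 of them changed at least 2-fold. This last count rests on the offset of 2 in the values: with offsets of 1 and 0.1 it was 320 and 619. In 9127 of the 11945 tested genes the 3 values of one group all lay above those of the other, which 10% of genes do by chance. For the genes named here outside the MLX network, and for Mlx, the SE was 0.02 to 0.0696 and the highest limma adjusted p was 3.44e-06. With each library centred on its median 4511 genes were higher and 3775 lower, and with quantile normalization 3994 and 4343, so the balance of rises and falls depends on the scaling. Against the non-targeting control 8355 genes differed, of which 4175 had the same direction as against the GFP control and 2022 the opposite one, and 48 changed at least 2-fold in the same direction against both.

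**Figure D3:**
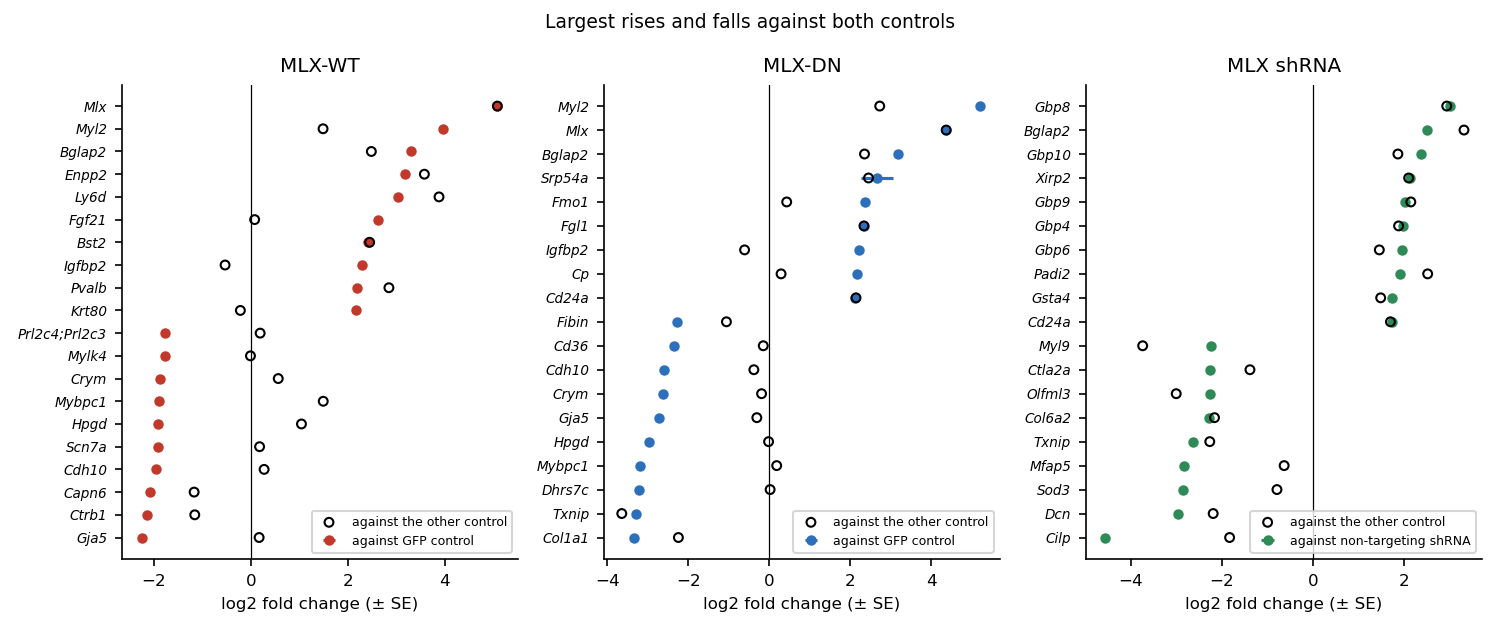
Log2 fold changes (x axis, log2(FPKM + 2) scale) of genes among the 10 largest rises and 10 largest falls in each comparison, with filled points and SE bars for the comparison's own control and open points for the other control. For MLX-WT and MLX-DN many falls against the GFP control lie near 0 or above it against the non-targeting control, such as Hpgd with MLX-WT (-1.91 and 1.04), while Txnip is low against both with MLX-DN and MLX shRNA.

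The dominant-negative form is meant to show which genes respond when MLX activity is lowered at the protein level. That activity was not measured here. Txnip, whose product restrains glucose uptake, fell from 30.2 ± 0.966 FPKM in the GFP control to 1.31 ± 0.176 with MLX-DN, a log2 change of -3.28 (-3.64 against the non-targeting control, where it stood at 39.3 ± 0.828). It overlaps the antisense gene Gm15441, which went from 14.3 ± 0.541 to 0.531 ± 0.0402 FPKM, and reads of the pair may not be told apart. Cell cycle genes fell and cholesterol synthesis genes rose against both controls, but with an estimated correlation the cholesterol list did not pass (adjusted p = 0.0930) against the GFP control, where 13 of 20 rose and 6 fell, and passed against the non-targeting control (adjusted p = 0.00202). The type I collagen genes Col1a1 and Col1a2 went from 442 ± 4.68 and 527 ± 2.66 FPKM to 41.9 ± 2.54 and 202 ± 6.75 (-3.34 and -1.37, or -2.24 and -0.63 against the non-targeting control), and the growth factor gene Igf2 from 173 ± 1.78 to 67.7 ± 2.23 (-1.33).

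Among the largest rises with MLX-DN, apart from Mlx, Myl2 rose by 5.21, Bglap2 by 3.17, the liver-type secreted protein gene Fgl1 by 2.34 and the surface antigen gene Cd24a by 2.12, and each also rose against the non-targeting control (2.73, 2.36, 2.34 and 2.15). Srp54a of the signal recognition particle was at 2.66 (SE 0.388, limma adjusted p = 1.13e-05), and is uncertain because it may share reads with Srp54b and Srp54c. Fmo1 (2.36) and Cp (ceruloplasmin, 2.18) rose mostly relative to the GFP control, with 0.43 and 0.29 against the other, and Igfbp2 turned from 2.21 to -0.61. Among the falls, Col1a1 and the secreted protein gene Fibin were lower than in both controls (-2.28 and -1.06 for Fibin). The remaining 7 of the 10 largest falls, apart from Txnip, were smaller or turned against the other control. Dhrs7c (-3.21), Mybpc1 (-3.20), Hpgd (-2.97), Gja5 (-2.73), Crym (-2.62), Cdh10 (-2.60) and the fatty acid transporter gene Cd36 (-2.35) stood at 0.02, 0.19, -0.01, -0.30, -0.19, -0.38 and -0.15 against the non-targeting control.

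Of 34 cell cycle genes 33 fell with MLX-DN and none rose (33 when adjusted over the list alone; camera adjusted p = 1.97e-09, and adjusted p = 0.0202 with an estimated correlation). The median was -0.80, or -0.41 against the non-targeting control (adjusted p = 9.52e-10). Mcm2 (-1.32), Mcm3 (-1.28), the mitotic kinase gene Cdk1 (-0.96) and topoisomerase gene Top2a (-0.95) were examples, at -0.82, -1.0, -0.60 and -0.67 against the other control. Of 20 cholesterol synthesis genes 13 rose and 6 fell (19 when adjusted over the list alone; adjusted p = 0.00822, and adjusted p = 0.0930 with an estimated correlation), and 15 rose against the non-targeting control (adjusted p = 9.52e-10). They included Idi1 (1.02), Sc4mol (0.96) and Fdps (0.61), with 0.96, 0.72 and 0.71 against the other control. Of 28 genes of ER stress and ATF4 20 rose and 4 fell (24 when adjusted over the list alone; adjusted p = 2.05e-06, and adjusted p = 0.186 with an estimated correlation). Those that rose included the chaperone genes Hspa5 (1.20) and Calr (1.45), Herpud1 (1.37) and Asns (0.89). Of 18 hypoxia response genes 13 rose and 2 fell (15 when adjusted over the list alone; adjusted p = 0.00159, and adjusted p = 0.0930 with an estimated correlation). Bnip3 was at 1.53 and the vascular growth factor gene Vegfa at 0.85. Of 30 ribosomal protein genes 25 fell and none rose (25 when adjusted over the list alone; adjusted p = 0.00159, and adjusted p = 0.887 with an estimated correlation). Rpl8 was at -0.76 and Rps19 at -0.53. These 3 lists did not pass against the non-targeting control (adjusted p = 0.690, 0.995 and 0.230), where Hspa5 was at 0.31, Calr at -0.21, Herpud1 at 0.04, Asns at 0.08, Bnip3 at 0.31, Vegfa at 0.22, Rpl8 at -0.16 and Rps19 at -0.06. Quantile normalization ended the ribosomal call (adjusted p = 0.162; 9.31e-05 to 0.887 over its alternatives).

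Sarcomere genes split with MLX-DN, with 19 of 49 higher and 27 lower (46 when adjusted over the list alone; adjusted p = 0.830). The fast myosin gene Myh4 (-2.26) and cardiac actin gene Actc1 (-1.39) were low against the GFP control and high against the non-targeting control (0.99 and 0.24), where 41 of the 49 sarcomere genes were higher (adjusted p = 3.96e-20, and adjusted p = 0.115 with an estimated correlation). The myogenic factor genes Mef2c (-1.43) and Myf5 (-1.11) turned likewise, to 0.16 and 0.12, in a list of 18 with 6 higher and 8 lower (14 when adjusted over the list alone; adjusted p = 0.970). Of 63 secreted muscle factors 25 rose and 31 fell (56 when adjusted over the list alone; adjusted p = 0.830). Igf2 and the growth factor gene Ptn (-1.97) fell against both controls (-0.86 and -0.39). Of 33 matrix genes 19 fell and 9 rose (28 when adjusted over the list alone; adjusted p = 0.291), with Thbs2 (thrombospondin 2) at -1.42 and Timp3 at 1.89 (-0.87 and 0.93 against the non-targeting control). Against that control 27 fell and 5 rose (adjusted p = 0.000234, and adjusted p = 0.456 with an estimated correlation). Id1 (-1.28) and Id3 (-0.98), inhibitors of differentiation that BMP signals induce, fell in a list that did not pass (adjusted p = 0.830). Of 15 glucose-responsive targets 5 rose and 10 fell (15 when adjusted over the list alone; adjusted p = 0.830), so that Txnip fell while Scd1 rose (0.52).

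By limma, 9723 of 11945 genes differed between MLX-DN and the GFP control, 3892 higher and 5831 lower, and 462 changed at least 2-fold (709 and 1196 with offsets of 1 and 0.1). Groups did not overlap in 9986 of the 11945 genes, against 10% by chance, and the genes named outside the MLX network, and Mlx, had an SE of 0.0189 to 0.0596 and a limma adjusted p of at most 1.79e-10, apart from Srp54a. Median centring gave 5017 higher and 4660 lower, and quantile normalization 4917 and 4774. Against the non-targeting control 8331 genes differed, 5971 had the same direction against both controls and 28 of these changed at least 2-fold against both.

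Lowering Mlx with a hairpin asks the same question by loss of the transcript, against its own non-targeting control. Extracellular matrix genes had the lowest median of the 29 lists, -0.94, and fell as a list against both controls (camera adjusted p = 1.28e-10 and 0.000357), though against neither with an estimated correlation (adjusted p = 0.211 and 0.563). Dcn (decorin) went from 17 ± 0.384 to 0.445 ± 0.0962 FPKM (-2.96), Col3a1 from 984 ± 32.0 to 291 ± 4.44 (-1.75) and Thbs2 from 52.2 ± 1.11 to 9.63 ± 0.0702 (-2.22). Txnip fell from 39.3 ± 0.828 to 4.72 ± 0.196 FPKM (-2.62) and Igf2 from 125 ± 0.986 to 32.2 ± 0.609 (-1.89). A group of guanylate-binding protein genes, known as interferon-induced GTPases, rose: Gbp8 went from 3.34 ± 0.253 to 41.1 ± 0.678 FPKM (3.02).

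The genes named here among the 10 largest rises and 10 largest falls with MLX shRNA kept their direction against the GFP control. The other guanylate-binding genes among them were Gbp10 (2.38), Gbp9 (2.02), Gbp4 (1.98) and Gbp6 (1.96), near copies that may share reads and are uncertain one by one. Bglap2 rose by 2.51, the actin-binding gene Xirp2 by 2.13, Padi2 (a protein deiminase) by 1.92, Gsta4 (a glutathione transferase) by 1.74 and Cd24a by 1.73. The falls included Cilp (a cartilage matrix protein, -4.56), Dcn, Sod3 (extracellular superoxide dismutase, -2.85), Mfap5 (a microfibril protein, -2.84), Txnip, Col6a2 (type VI collagen, -2.29), Olfml3 (-2.26), Ctla2a (-2.25) and Myl9 (-2.23). Cilp, Sod3 and Mfap5 were higher in the non-targeting control than in the GFP control (2.74, 2.07 and 2.21), and against the GFP control they were at -1.83, -0.79 and -0.63.

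Of 33 matrix genes 27 fell and 3 rose with MLX shRNA (30 when adjusted over the list alone; camera adjusted p = 1.28e-10, and adjusted p = 0.211 with an estimated correlation). Bgn was at -1.84. Of 10 fibroblast markers 9 fell and none rose (9 when adjusted over the list alone; adjusted p = 5.87e-05, and adjusted p = 0.0129 with an estimated correlation): the growth factor receptor gene Pdgfrb was at -1.50 and S100a4 at -1.13. Against the GFP control that list did not pass (adjusted p = 0.132). Of 63 secreted muscle factors 41 fell and 14 rose (56 when adjusted over the list alone; adjusted p = 0.000600, and adjusted p = 0.204 with an estimated correlation). They included Igf2 and the angiopoietin gene Angpt1 (-1.92), and Igfbp7 of the IGF axis list was at -2.02. Of 19 TGF-beta and SRF targets 14 fell and 3 rose (17 when adjusted over the list alone; adjusted p = 0.0111, and adjusted p = 0.429 with an estimated correlation). Myl9 and Cnn1 (-1.59) fell and Ankrd1 rose (1.09). The secreted factor and TGF-beta lists did not pass against the GFP control (adjusted p = 0.418 and 0.414).

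Of 34 cell cycle genes 33 fell with MLX shRNA and 1 rose (34 when adjusted over the list alone; adjusted p = 1.03e-11, and adjusted p = 0.00902 with an estimated correlation). Top2a (-0.80) and the proliferation marker gene Mki67 (-0.69) fell and Ccnd1 rose (1.21). Of 28 genes of ER stress and ATF4 20 rose and 7 fell (27 when adjusted over the list alone; adjusted p = 0.00168, and adjusted p = 0.429 with an estimated correlation). Asns rose by 0.59 and Psat1 by 0.50, while the transcription factor gene Cebpb fell (-1.55). Sarcomere genes rose, 33 of 49 against 10 that fell (43 when adjusted over the list alone; adjusted p = 7.94e-07, and adjusted p = 0.429 with an estimated correlation): the embryonic myosin gene Myh3 by 1.0, Myh1 by 0.95 and the calcium store gene Casq2 by 0.94. Against the GFP control 27 of the 49 fell and 19 rose (adjusted p = 0.241), and these 3 genes were at 0.07, 0.63 and 0.59. The sarcomere list was also higher than in the non-targeting control with MLX-WT and MLX-DN (camera adjusted p = 1.18e-20 and 3.96e-20). Neither of these 2 calls held with an estimated correlation. The rise of sarcomere genes is thus not particular to MLX shRNA, and the 3 comparisons share the non-targeting libraries. Of 26 oxidative phosphorylation genes 17 rose and 7 fell (24 when adjusted over the list alone; adjusted p = 0.0197, and adjusted p = 0.429 with an estimated correlation). Those that rose included Cox6a2 (0.69) and Ndufb5 (0.32). Of 18 fatty acid oxidation genes 12 rose and 5 fell (17 when adjusted over the list alone; adjusted p = 0.0283, and adjusted p = 0.388 with an estimated correlation). Etfa (0.49) and Cpt2 (0.57) rose and Cpt1a, the entry step to mitochondria, fell (-0.66). Of 20 genes of the tricarboxylic acid cycle 11 rose and 5 fell (16 when adjusted over the list alone; adjusted p = 0.0428, and adjusted p = 0.435 with an estimated correlation). Pdhb was at 0.37 and Idh2 at -0.67. These 3 mitochondrial lists did not pass with quantile normalization (adjusted p = 0.309, 0.106 and 0.341; 0.00953 to 0.873, 0.00953 to 0.908 and 0.0145 to 0.764 over their alternatives) or against the GFP control (adjusted p = 0.873, 0.908 and 0.764), where Cox6a2, Ndufb5, Etfa and Cpt2 were at 0.23, 0.09, 0.23 and 0.24, and the tricarboxylic acid cycle list also lost the call without non-targeting replicate 3 (adjusted p = 0.0532). Removal of trends over GC content and length ended all 3 calls (adjusted p = 0.0871, 0.0626 and 0.0685). Median centring ended those of fatty acid oxidation (0.0513) and the tricarboxylic acid cycle (0.0502). The latter was also lost with the stricter filter (0.0595), with no trend in the variance (0.0527) and with only the groups of the comparison in the fit (0.0522). The 3 lists passed in 16, 15 and 11 of 20 alternatives. They were also higher than in the non-targeting control with MLX-WT (adjusted p = 9.99e-06, 0.00175 and 0.0135) and with MLX-DN (adjusted p = 3.09e-07, 0.000376 and 0.000234), so this rise is not particular to MLX shRNA. The comparisons with the non-targeting control share its libraries, so a rise with the constructs cannot be told apart from low values in that control. None of these calls held with an estimated correlation (adjusted p = 0.149, 0.149 and 0.296 with MLX-WT, and adjusted p = 0.106, 0.113 and 0.180 with MLX-DN). Of the 15 glucose-responsive targets of MLX partners 3 rose and 8 fell (11 when adjusted over the list alone; adjusted p = 0.125, and adjusted p = 0.429 with an estimated correlation), with a median of -0.21 and with Txnip and Klf10 (-0.79) among those that fell. This list passed with the stricter filter alone, at a median of -0.29 (adjusted p = 0.0294; 0.0294 to 0.429 over its alternatives). In other lists that did not pass, the myogenic repressor gene Msc (musculin) rose (1.57) and Id1 fell (-0.74).

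By limma, 8369 of 11945 genes differed between MLX shRNA and the non-targeting shRNA, 3674 higher and 4695 lower, and 180 changed at least 2-fold (267 and 575 with offsets of 1 and 0.1). Groups did not overlap in 8295 of the 11945 genes, against 10% by chance, and the genes named outside the MLX network, and Mlx, had an SE of 0.0217 to 0.0716 and a limma adjusted p of at most 2.62e-08. Median centring gave 4675 higher and 3716 lower, and quantile normalization 4383 and 3943. Against the GFP control 9558 genes differed, 660 by at least 2-fold, 5898 in the same direction as against the non-targeting control, and 116 by at least 2-fold in the same direction against both.

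**Figure D4:**
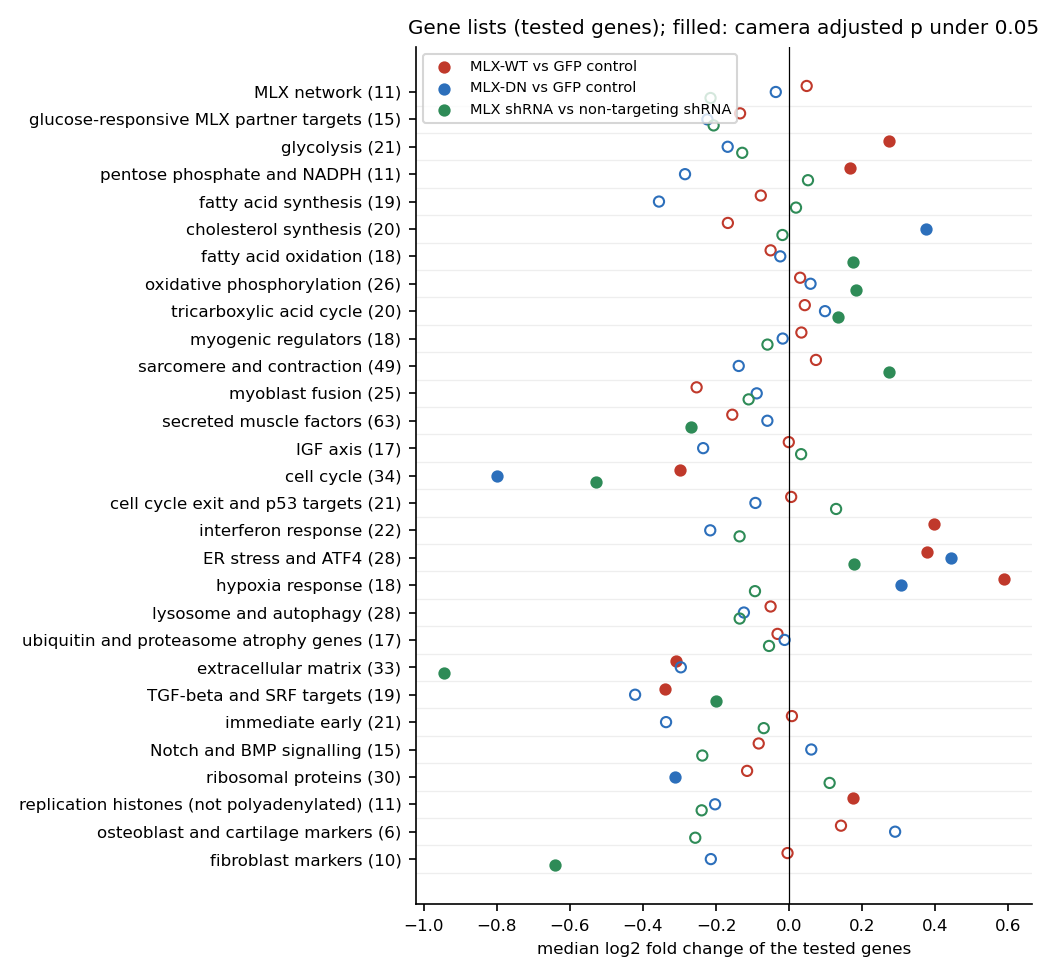
Median log2 fold change (x axis, log2(FPKM + 2) scale) of the tested genes of 29 lists in the 3 comparisons with a control, with the number of tested genes in brackets and filled points where the camera adjusted p is under 0.05. Cell cycle genes have medians of -0.30, -0.80 and -0.53, and the lowest median is that of the extracellular matrix with MLX shRNA (-0.94).

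The remaining lists did not pass the camera test, 20 with MLX-WT (adjusted p = 0.0758 to 0.965), 24 with MLX-DN (0.291 to 0.997) and 19 with MLX shRNA (0.0554 to 0.939). They include fatty acid synthesis, lysosome and autophagy genes, ubiquitin and proteasome atrophy genes, p53 targets, myoblast fusion genes and osteoblast and cartilage markers (adjusted p = 0.1, 0.294 and 0.551 for the last). Some passed in an alternative. Myoblast fusion genes fell with quantile normalization for MLX-WT (adjusted p = 0.0108; 0.0108 to 0.664 over its alternatives) and MLX shRNA (0.0284; 0.0284 to 0.62), and for MLX-WT against the non-targeting control (adjusted p = 0.0161, and adjusted p = 0.388 with an estimated correlation). With MLX-WT, cholesterol synthesis genes fell with no filter (adjusted p = 0.0234; 0.0234 to 0.266) and ribosomal protein genes after removal of trends over GC content and length (0.00981; 4.42e-08 to 0.821), though ribosomal protein genes were higher against the non-targeting control (adjusted p = 4.42e-08, and adjusted p = 0.200 with an estimated correlation). Immediate early genes were lower with MLX-DN than in the non-targeting control (adjusted p = 0.00115, and adjusted p = 0.243 with an estimated correlation), and interferon response genes lower with MLX shRNA than in the GFP control (adjusted p = 0.0444, and adjusted p = 0.174 with an estimated correlation). Lists of adipocyte, immune cell and endothelial or smooth muscle markers had only 4, 3 and 4 genes above the filter and were not tested, and the table held none of the 13 mitochondrially encoded genes. In several lists that did not pass, the median, the mean and the camera direction differed in sign. They include sarcomere and immediate early genes with MLX-WT, myogenic regulators, secreted factors, Notch and BMP signalling and the MLX network with MLX-DN, and myogenic regulators and the IGF axis with MLX shRNA. Against the other control the same held for hypoxia and ribosomal protein genes with MLX-DN and for fatty acid oxidation with MLX shRNA.

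The MLX constructs were also compared with each other, which needs no control group. Runs of neighbouring genes, described below, differed here too. Of 22 interferon genes 20 were lower and 2 higher with MLX-DN than with MLX-WT (22 when adjusted over the list alone; camera adjusted p = 1.84e-07, and adjusted p = 0.00271 with an estimated correlation). Bst2 differed by -2.40. Of 20 cholesterol synthesis genes 16 were higher and 2 lower (18 when adjusted over the list alone; adjusted p = 4.27e-06, and adjusted p = 0.00480 with an estimated correlation). Idi1 was at 1.14. Cell cycle genes were lower with MLX-DN in 33 of 34 cases (33 when adjusted over the list alone; adjusted p = 4.32e-11, and adjusted p = 0.00480 with an estimated correlation). Txnip differed by -3.59, Enpp2 by -3.65, Ly6d by -3.59, Col1a1 by -1.78, Thbs2 by -2.37 and Myl2 by 1.25. Glycolysis (16 of 21 lower), pentose phosphate and NADPH (9 of 11), ribosomal protein (23 of 30), replication histone (11 of 11) and sarcomere genes (29 of 49) were lower with MLX-DN and myoblast fusion genes higher (15 of 25), with adjusted p = 0.00137, 0.01, 0.000928, 0.00678, 0.0180 and 0.0429, and adjusted p = 0.573, 0.160, 0.580, 0.150, 0.700 and 0.604 with an estimated correlation. Adjusted over the list alone, 19, 10, 25, 11, 41 and 22 of their members differed. By limma 8618 of 11945 genes differed, 3967 higher and 4651 lower, and 157 by at least 2-fold (263 and 540 with offsets of 1 and 0.1). Median centring gave 4382 higher and 4290 lower and quantile normalization 4709 and 4043, so which side is larger depends on the scaling.

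Calls of the MLX-DN and MLX shRNA comparisons, which share no libraries, overlapped in direction. Both rose for 1640 genes and both fell for 2761, while 1197 and 2292 follow from the numbers called if the lists were independent (exact one-sided hypergeometric p = 1.28e-76 and 1.28e-69, given as a description, since genes are not independent). With median centring 2447 rose and 1905 fell in both, and with quantile normalization 2252 and 2009, so which of the 2 is larger depends on the scaling. Txnip (-3.28 and -2.62), Igf2 (-1.33 and -1.89), Thbs2, Col1a2 and Id1 fell and Bglap2, Cd24a and Gbp8 (1.22 and 3.02) rose in both. In 2575 genes the directions were opposite, and the correlation of log2 changes across genes was 0.229, over genes that are not independent replicates. MLX-WT and MLX-DN were called in the same direction in 6346 genes and in opposite directions in 912, beside 1075 rising and 2490 falling together if independent. They share the GFP control, and the correlation of their changes across genes was 0.683, while unchanged groups against the same control gave 0.501 on average over 100 simulations and no gene called in both. The covariance was 0.104 beside a simulated 0.00123. The simulation counts the spread between the shared control libraries, which gives little of this covariance, but not a deviation common to all 3. With 3 control libraries the control could not be split into 2 parts with replicates. Part of the excess may thus come from such a deviation. The non-targeting shRNA, which carries no MLX construct, was compared with the same GFP control. Its changes correlated with those of MLX-DN at 0.825 and with those of MLX-WT at 0.600. Agreement of this size against the GFP control is therefore not particular to MLX constructs. MLX-WT and MLX shRNA, raised against lowered MLX, rose together in 1409 genes (1015 if independent) and fell together in 2552 (2005), and went opposite ways in 1098 and 1109 genes (1297 and 1569 if independent), with the MLX-WT value higher and lower. With median centring 2234 rose and 1711 fell together, and with quantile normalization 1848 and 1929. For rising and falling together in this pair the exact one-sided hypergeometric p was 2.39e-66 and 1.5e-95, again as a description. The correlation of log2 changes across genes was 0.189. This pair shares no libraries either, so the overlap in direction is not particular to the constructs meant to lower MLX.

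The effects of the constructs were also tested against each other with limma. The effect of MLX-DN and the effect of MLX shRNA, each against its own control, differed in 8937 genes, and those of MLX-WT and MLX shRNA in 7807. As each effect is taken from a different control, these differences contain the difference between the 2 controls. Cilp rose with MLX-DN against the GFP control by 1.90 and fell with MLX shRNA (-4.56), a difference of 6.46 (SE 0.0420, limma adjusted p = 3.32e-21), while the controls differed by 2.74. Against the non-targeting control Cilp was at -0.84 with MLX-DN. Thbs2 rose with MLX-WT by 0.95 and fell with MLX shRNA (-2.22), a difference of 3.17 (SE 0.0327, limma adjusted p = 3.17e-18), while the controls differed by -0.54. Tmem86a, a transmembrane protein gene, was at 21.1 ± 0.376 FPKM in the GFP control, 69.5 ± 1.06 with MLX-WT, 10.7 ± 0.0755 in the non-targeting control and 2.52 ± 0.182 with MLX shRNA, and its effects differed by 3.12.

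The GFP and non-targeting controls carry no MLX construct, and their comparison gives the background of the others. Sarcomere genes were lower in the non-targeting control in 40 of 49 cases and higher in 7 (48 when adjusted over the list alone; camera adjusted p = 4.82e-10, and adjusted p = 0.288 with an estimated correlation), and Myh4 stood at 158 ± 2.88 FPKM in the GFP control and 14.8 ± 0.768 in the other (-3.26). Mybpc1 (-3.38), Hpgd (-2.95), the collagen gene Col6a3 (-1.87) and Cdh10 (-2.22) were also lower, and Cilp (2.74), Gpt2 (1.82), Zfp330 (1.53), Cd80 (1.57) and Postn (1.69) higher. Genes of ER stress and ATF4 (26 of 28; adjusted p = 3.56e-09) and hypoxia (15 of 18; adjusted p = 0.000238) were higher in the non-targeting control, and cell cycle (28 of 34; adjusted p = 6.83e-07), ribosomal protein (27 of 30; adjusted p = 3.39e-07) and fatty acid oxidation genes (12 of 18; adjusted p = 0.0181) lower, and adjusted over the list alone 28, 17, 30, 27 and 13 of their members differed. None of these lists passed with an estimated correlation (adjusted p = 0.1, 0.0744, 0.0744, 0.288 and 0.288). By limma 8854 of 11945 genes differed, 4421 higher and 4433 lower, and 300 by at least 2-fold (444 and 812 with offsets of 1 and 0.1). Across genes, the change of MLX-DN from the GFP control correlated with that of the non-targeting shRNA at 0.825, and that of MLX-WT at 0.600. For MLX-DN the covariance was 0.141, of which 0.00123 follows from the spread between the 3 GFP control libraries. A deviation common to all 3 would enter both changes and is not counted in that value.

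In the order of genes along the GRCm38 assembly, 125 neighbouring genes of chromosome 8 with a mean FPKM of 5 or more, from Arhgap10 to Rrad, had a median log2 difference of 1.16 between the non-targeting and GFP controls, and 122 of them were higher. Their median against the GFP control was 0.59 with MLX-WT, 1.03 with MLX-DN and 1.07 with MLX shRNA, and -0.04 for MLX shRNA against the non-targeting control. Zfp330, Gpt2, Herpud1 and Calr lie in this run. Of 215 such genes that differed at least 2-fold between the controls, 75 (34.9%) lay in runs of this kind. On chromosome 15, 10 neighbours from Apol9a to Kctd17 had a median of -0.70 between the controls and -0.93 with MLX-DN. No run was found for MLX shRNA or MLX-DN against the non-targeting shRNA, and MLX-WT against it had 4. MLX-DN against MLX-WT had 5 runs, with medians of 0.60 and 0.55 on chromosome 8, -0.60 on chromosome 11, and -0.86 and -0.65 on chromosome 15. They held 14.1% of the 92 genes of this expression that differed at least 2-fold between these 2 groups.

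**Figure D5:**
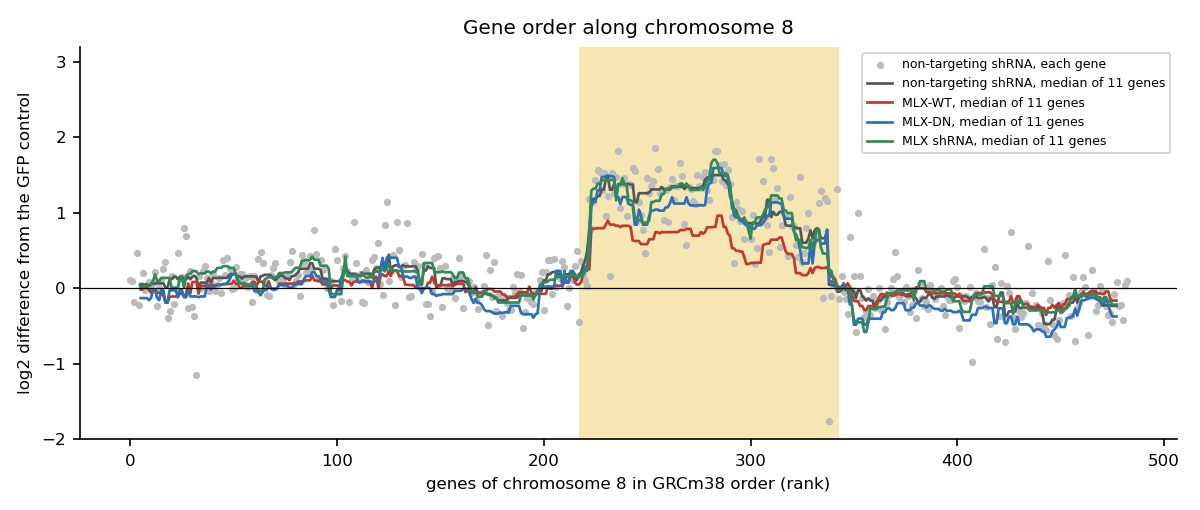
Log2 differences from the GFP control (y axis, log2(FPKM + 2) scale) of 483 genes of chromosome 8 in GRCm38 order (x axis, rank), with points for single genes in the non-targeting control and lines for the median of 11 neighbours in each of the other 4 groups. In the shaded run of 125 genes the median is 1.16 for the non-targeting control, 1.03 for MLX-DN, 1.07 for MLX shRNA and 0.59 for MLX-WT.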

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

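Of the tests in this part, those of the differences of effects, of the other splits of the samples, and of GC content, segment copies and neighbouring genes for the chromosome patterns were set before their results were seen, and the remaining tests were chosen after the result was seen.

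Effects of the constructs differed from each other in tests of the difference itself. Each effect is taken from its own control. A difference of effects is thus the direct difference between the construct groups plus the difference between the controls (non-targeting minus GFP). The side given for a gene is therefore not by itself its order between the constructs. The MLX-DN effect and the MLX shRNA effect, each against its own control, differed in 8937 genes. Those of lowest p, which are not in all cases those of largest size, include Cilp (6.46 log2), Myl2 (5.16), Sod3 (4.81) and Mfap5 (4.43) on the higher side for MLX-DN and Tspan7 (-3.13), Hpgd (-2.93), Myh4 (-2.68), Ly6e (-1.98) and Actc1 (-1.84) on the lower side. Of these genes, Cilp (2.74), Myl2 (2.48), Sod3 (2.07) and Mfap5 (2.21) were higher in the non-targeting than in the GFP control. Tspan7 (-2.28), Hpgd (-2.95), Myh4 (-3.26), Ly6e (-0.61) and Actc1 (-1.63) were lower there. The values of Hpgd and Actc1 are thus close to the difference between the controls. Despite its negative value, Myh4 was higher with MLX-DN (31.4 FPKM) than with MLX shRNA (20.4). The MLX-WT and MLX shRNA effects differed in 7807 genes, and those of lowest p include Mlx (6.96), Enpp2 (3.39), Thbs2 (3.17) and Tmem86a (3.12) on the higher side for MLX-WT and Gbp8 (-2.53), Tspan7 (-2.52), Hpgd (-1.88), Mylk4 (-1.63) and Postn (-1.56) on the lower side. Between the controls these genes were at 0.00, -0.41, -0.54, -0.86, -0.07, -2.28, -2.95, -1.77 and 1.69. The values of Tspan7 and Mylk4 are thus of about the size and sign of that difference. That of Hpgd has its sign but is smaller, and Hpgd was higher with MLX-WT (2.275 FPKM) than with MLX shRNA (0.0279). Only 1 of 100 splits of the same samples, the real one, gave as many genes for each. The highest of the others gave 6584 and 4066. This speaks only against a chance assignment of single libraries, not of cultures, since the libraries of a group may be technical. Libraries of a group were so alike that the real split ranks first for any difference between groups, so its rank does not test whether the effects differ. The 100 splits pair 10 of each comparison, so some of the others keep the real grouping of 1 of the 2 comparisons.

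For the comparisons of 3 libraries with 3, only 10 splits exist, too few for a share under 0.05. The real split gave 8400 genes for MLX-WT, 9723 for MLX-DN, 8369 for MLX shRNA, 8618 for MLX-DN against MLX-WT and 8854 for the controls, and the highest other split gave 0 in each. In the real splits 9, 5 and 10 lists passed for MLX-WT, MLX-DN and MLX shRNA, and at most 6, 6 and 8 in another split. As many lists as in the real split passed in 1, 5 and 1 of the 10 splits, the real one included.

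The GFP and non-targeting controls differed in 8854 genes, which bears on every comparison with the GFP control. Trends over GC content and gene length do not account for it as a whole, since 8728 genes differed after their removal. Nor does the deepest GFP control library (8415 genes differed without replicate 1). The chromosome 8 run holds only 152 tested genes, so by its size alone it could not account for the count (8708 genes differed outside it). The kind of vector, the cells each virus was put into, and their handling go with the control groups here and stay open as untested, and no biological explanation was tested.

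The run of chromosome 8 genes that were higher in the other 4 groups than in the GFP control had a median of 1.16 before and 1.20 after removal of the trends over GC content and length, which argues against these trends. The highest 11-gene median over 100 random gene orders was 0.66, which argues against a chance order of unrelated genes. A difference in the number of copies of the segment may be a source, and cannot be told apart here from a shared change of expression. Its higher and lower expressed genes had medians of 1.34 and 0.93, a difference of 0.41, beyond the bound of 0.3 written beforehand, but that bound did not allow for the offset of 2, which narrows the changes of low genes, and with an offset of 0.1 the difference was 0.29. With 0.59 for MLX-WT and 1.03 for MLX-DN, the run differs among groups that share a control, and no DNA was analysed here.

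Guanylate-binding genes of chromosome 5 rose with MLX shRNA, with Gbp8 at 3.02, while Gbp2 and Gbp3 of another cluster were at -0.04 and -0.01. If all reads of the near copies came from a single gene, their ratio would stay the same. The ratio of Gbp8 to Gbp6 FPKM was instead 2.11 ± 0.0903 with the non-targeting shRNA and 3.46 ± 0.268 with MLX shRNA (SD, n = 3). The latter was 1.64 times as high, with no overlap of libraries. In the GFP control the ratio was 1.18 ± 0.023. Where a copy also has reads of its own, the ratio can change too, so it does not argue against reads passed on from Gbp8. Of 22 interferon response genes 13 fell and 1 rose, which argues against a general interferon response, and the 20 tested genes beside the Gbp genes had a median of -0.04 (-0.85 to 0.27), which argues against a shift of the whole segment. Partial sharing of reads among the copies stays open. Gbp8, Gbp9, Gbp4, Gbp10 and Gbp6 were also higher with MLX-DN, which carries no hairpin (1.22, 0.91, 0.58, 0.57 and 0.46 against the GFP control, 1.29, 0.78, 0.67, 1.08 and 0.95 against the other), so a hairpin is not needed for a rise. They were higher with MLX-WT too (0.49, 0.58, 0.41, 0.20 and 0.11, or 0.56, 0.45, 0.50, 0.71 and 0.61). A change of these genes with lowered MLX stays a hypothesis, and the source of the larger rise with MLX shRNA stays open, since results were not given separately for more than 1 hairpin.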

How the results depend on the processing

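The alternatives with GC and length trends removed, with calls in the same direction against both controls, without the chromosome 8 run, and with the other control for Mlx and for counts of lists were chosen after the result was seen, and the others were planned. Of the 17 results that answer a comparison, 338 values stayed within the limits set for a change and 12 moved. Counts of changed genes without a limit on size did not move beyond their limits under any offset, filter, scaling, variance model, set of libraries or left-out library. A 2-fold limit left 200 genes for MLX-WT, 462 for MLX-DN and 180 for MLX shRNA, by its own construction, and these 2-fold counts rest on the offset (320, 709 and 267 with an offset of 1, and 619, 1196 and 575 with 0.1). The same direction against both controls held for 4175 and 5971 genes for MLX-WT and MLX-DN. With an estimated correlation 2, 1 and 2 lists passed for MLX-WT, MLX-DN and MLX shRNA instead of 9, 5 and 10. With the other control 12 lists passed for MLX-WT, 8 for MLX-DN and 5 for MLX shRNA, and with an estimated correlation as well 1, 2 and 1. The correlation of MLX-DN and MLX shRNA effects across genes, 0.229, was 0.209 to 0.249 with 1 library left out, the lowest without MLX shRNA replicate 1 and the highest without MLX shRNA replicate 2. With 1 library left out, genes changed were 7892 to 8007 for MLX-WT, 9449 to 9534 for MLX-DN and 7917 to 8176 for MLX shRNA, and the log2 change of Mlx was 5.058 to 5.097, 4.351 to 4.39 and -1.979 to -1.823.

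With the non-targeting shRNA as the control, 27 values of named genes turned direction, and in no other setting did one turn. For MLX-WT these were Max (-0.113), Mycl1 (-0.268), Txnip (-0.049), Herpud1 (-0.286), Slc16a1 (-0.155), Myl9 (0.69), Myl4 (0.664), Myog (-0.127), Rbm24 (-0.198), Igfbp2 (-0.533), Krt80 (-0.217), Gja5 (0.169), Cdh10 (0.272), Scn7a (0.179), Hpgd (1.042), Mybpc1 (1.491), Crym (0.563) and Prl2c4;Prl2c3 (0.19). For MLX-DN they were Mycl1 (-0.066), Calr (-0.214), Myh4 (0.993), Actc1 (0.242), Mef2c (0.161), Myf5 (0.118), Igfbp2 (-0.608), Dhrs7c (0.023) and Mybpc1 (0.186). List medians that went with a turned direction were 0.056 for cell cycle, -0.13 for ER stress and ATF4 and 0.239 for ribosomal proteins with MLX-WT, and 0.4 for sarcomere genes, -0.124 for ER stress and ATF4 and -0.007 for ribosomal proteins with MLX-DN. With the GFP control for MLX shRNA they were -0.174 for sarcomere genes and -0.255 for ribosomal proteins. The cause was not tested. Another 7 values of named genes no longer passed under the non-targeting control and 1 (Mlxip with MLX shRNA) under the GFP control, Mlxip with MLX-WT lost its call in 7 settings, and 2 values passed only in an alternative. The stricter filter left out 8 values of named genes.

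Of the lists, 1648 values kept direction and side of the threshold, 54 no longer passed and 24 passed only in the alternative. With 1 library left out, ribosomal proteins with MLX shRNA passed without non-targeting replicate 1 (adjusted p = 0.0381) or MLX shRNA replicate 1 (0.0113; 0.00179 to 0.915 over its alternatives), and glycolysis without non-targeting replicate 3 (0.0478) or MLX shRNA replicate 2 (0.0392; 0.00701 to 0.62). Both also passed with no filter, and glycolysis with quantile normalization. The cause was not tested. Samples with the same replicate number deviated together only weakly: 4 of 30 pairs correlated above 0.1 (-0.093 to 0.18). Still, 10 of 15 samples correlated best with a library of their own number. In each other group 1 of the 3 libraries carries that number, so this is more often than an even pick would give. With the number as a block, 8427 genes changed for MLX-WT, 9754 for MLX-DN, 8394 for MLX shRNA, 8642 between MLX-DN and MLX-WT and 8861 between the controls, and the differences of effects held for 8941 and 7836 genes. The block added a call for ribosomal proteins with MLX shRNA (adjusted p = 0.0491) and changed no other call of a list or a named gene. Depth limits values near 0.0182 to 0.0406 FPKM, the worth of 3 reads at 2000 bases.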

Other observations

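Genes in this part were chosen after their values were seen. The test of the order of MLX-WT, MLX-DN and MLX shRNA was set before its result was seen.

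Of the tested genes 6, listed here because they showed this order, were at least 0.5 log2 higher with MLX-WT and lower with MLX-DN, each against both controls, and lower with MLX shRNA against its own control, and none had the mirror order at that size. Ccl7, a chemokine gene, was at 15.9 ± 1.07 FPKM in the GFP control, 75.1 ± 3.11 with MLX-WT and 3.75 ± 0.535 with MLX-DN, and fell from 6.67 ± 0.575 to 0.462 ± 0.0791 with MLX shRNA. Lpl (lipoprotein lipase) was at 18.7 ± 0.329, 70.0 ± 1.66 and 2.89 ± 0.1 FPKM in the first 3 of these groups and went from 14 ± 0.101 to 8.55 ± 0.256 with MLX shRNA. Apoe (apolipoprotein E) was at 5.69 ± 0.0290, 15.8 ± 0.986 and 2.13 ± 0.159, and went from 9.24 ± 0.535 to 1.15 ± 0.0230. Il1rn, which encodes the interleukin 1 receptor antagonist, changed by 1.72, -1.90 and -0.93 log2, Ramp2 by 0.95, -0.91 and -0.76, and Thbs2 by 0.95, -1.42 and -2.22, each against its own control.

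With MLX-DN and with MLX shRNA, against either control, 2145 genes were lower and 987 higher, and no test here separated this from effects of the constructs themselves. These counts were made with the deposited scaling alone. For calls of both constructs against their own controls, median centring turned the balance (2447 rose and 1905 fell in both), so more falls than rises may not hold. Of the 2145 lower genes, 12 fell by at least 0.8 log2 in all 4 comparisons: Apoe, Col1a1, Dcn, Fibin, Gm15441, Gmnn, Igf2, Il1rn, Tcf19, Thbs2, Tk1 and Txnip. Gmnn (geminin) and Tk1 (thymidine kinase) are known for roles in DNA replication. Some also fell with MLX-WT against both controls: Col1a1 (-1.56 and -0.46), Dcn (-0.38 and -1.15) and Tcf19 (-0.80 and -0.31). The 8 that rose by as much were 1500017E21Rik, Bglap, Bglap2, Cd24a, Gbp8, Gm13031, Gsta4 and Padi2. Bglap and Bglap2 are near copies and uncertain one by one. Of the 8, all but Gm13031 and Padi2 also rose with MLX-WT against both controls: 1500017E21Rik (0.68 and 0.49), Bglap (1.22 and 1.12), Bglap2 (3.30 and 2.48), Cd24a (1.24 and 1.26), Gbp8 (0.49 and 0.56) and Gsta4 (0.94 and 1.19). These rises are therefore not specific to lowered MLX. Arrdc4, a close relative of Txnip and a known MondoA target, lay under the filter and was not tested.

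A hypothesis was that MLX raises a set of genes that its loss lowers, so that more genes would be called in this order than in the mirror order and than independent calls give. With the same controls 144 genes were called higher with MLX-WT and lower with MLX-DN and MLX shRNA, and 47 in the mirror order. Independent calls would give 186.8 and 130.6, and both orders lay below. These counts, too, were made with the deposited scaling alone. The effects of MLX-WT and MLX-DN were not independent, with a correlation of 0.683 across genes, of which the spread of the shared control libraries gives little (a covariance of 0.00123 of 0.104). The order was more frequent than its mirror (144 against 47), but the prediction also asked for more than independent calls give, and 144 lay below 186.8. By the bound set beforehand the prediction thus failed. That bound took the calls as independent and did not allow for the correlation of the effects, so it is not a measure of chance here. Why opposite calls were few was not tested, and the hypothesis stays open.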
